A study of Mus musculus with 26 samples.

How the data were processed

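Total RNA of pancreatic islets of C57BL/6J mice was measured on 26 Affymetrix whole-genome mouse arrays, 1 sample per array. Per the labels, islets of young (5 weeks) and old (56 weeks) mice recovered for 1 day at 11 mM glucose and were then cultured for 2 days at the stated concentration, or were used fresh. Per the labels' protocols, RNA was extracted with Trizol and labelled from 50 ng through 2 cycles of cDNA synthesis. The deposited values are probe set intensity on a linear scale, made by the authors with MAS5 per the submitters' processing notes, which give no version in the sources used here. On every array the mean intensity after trimming 2% at each end was 150, so the deposited values had already been scaled to 1 level by the authors. Values are whole numbers, zeros occur, and detection calls were not analysed here. The number of arrays limits the precision.

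The platform annotation names 1 gene symbol for 34945 of the 45101 probe sets, several for 932 and none for 9160, and 64 are controls. Symbols were updated through Entrez identifiers for 34741 probe sets, using a gene table of assembly GRCm38.p6 for names only. Probe sets with several symbols were not used. A few genes that bear on islets, among them Ins1 and Mafa, are not named by this annotation and were not analysed here.

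Intensities were transformed as log2(value + 16) with no further scaling, so a log2 change understates the change of dim genes. Probe sets above the array median on at least 2 of the 26 arrays were kept (23047 probe sets), and the brightest probe set stood for each gene, which left 12580 genes. A model with 12 group means was fitted with limma 3.58.1 in R 4.3.3 over all 26 arrays, with an intensity trend in the empirical Bayes step (14 residual and 5.33 prior degrees of freedom). Each of 14 comparisons is a contrast of those means. A gene is said to rise, fall or change where its Benjamini-Hochberg adjusted p is under 0.05 within a comparison, and log2 changes are given with limma's moderated standard error (SE). Signals are given as mean ± SD of the deposited values. The 26 gene lists of pathways and cell type markers were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. For a list, the count adjusted over all genes is given with the count adjusted over the list alone. Of 76 list calls in 364 tests, 8 held with an estimated correlation, and the p of that test is given beside each list. The labels call the replicates biological without saying whether mice were pooled, so the p-values measure the spread between these samples.

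The groups, comparisons, tests, gene lists and the alternatives of the processing were fixed before the data were examined, except for the array set blocks described next. The tests of explanations were set later, some of them after their results were seen. The rule for named genes was fixed at the same stage. Among genes past the threshold whose replicates do not overlap between groups (for means over ages or conditions, whose difference has the same sign in each), it takes the 10 largest rises and falls of the 4 main comparisons and 5 of the others. It adds up to 4 members of each list with the smallest adjusted p, and Ins2, Slc2a2, Pdx1, Txnip, Gcg and Sst.

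The ratio of the 5' to the 3' probe set of the Gapdh control separates the arrays into 2 sets that the labels do not name. In set A (12 arrays: all old groups, young fresh islets, and replicates 3 and 4 of young islets at 11 mM) it was 1.03 to 1.48. In set B (14 arrays) it was 0.1 to 0.169 for the 8 arrays of the other cultured young islets and 0.194 to 0.277 for the 6 time course arrays. A fit with the set as a fixed factor was added after the data were seen. Its set term is estimated from young islets at 11 mM alone, so that comparisons within 1 set keep their fold change and only their estimated spread becomes smaller, while comparisons across the sets are corrected by that 1 difference. Old and young islets at 3 and at 5.5 mM lie in different sets.

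Replicate numbers of the labels were checked for pairing by correlating the deviations of same-numbered arrays from their group means over all genes. The correlations were 0.17 to 0.42 over 6 pairs of cultured young groups and 0.55 to 0.63 over 3 pairs of time course groups, so the numbers were taken to pair the arrays there. They were 0.056 to 0.2 over 6 pairs of old groups and -0.01 to 0.035 between fresh and cultured young islets, where the numbers were not taken to pair. Between cultured young and old groups, whose mice differ, the correlations were 0.051 to 0.22 over 16 pairs. The lower correlations among cultured young groups lie in that range, so their pairing is less certain than that of the time course. The fit with the array set and a replicate block within each set has 8 residual degrees of freedom.

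The pipeline was tested on simulated data with the spread of these 12580 genes and 200 changed genes. For 11 against 3 mM in young islets it called 13.4% of genes changed by 0.5 on the log2 scale, 83.6% of those changed by 1 and 98.5% of those changed by 2, and 5 unchanged genes. For fresh old against fresh young islets the shares were 1.49%, 56.7% and 98.5%, with 10 unchanged genes called. A shifted list was called in each of the 6 simulated comparisons, and none of 25 unchanged lists was called in any of them. The simulated genes varied independently of each other and had no array set effect. The simulation therefore does not show how the list test behaves where genes of a list vary together.

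The alternatives were quantile normalization, an offset of 1, no filter or a filter at the 75th percentile, the mean over the probe sets of a gene, no intensity trend, only arrays of the same experiment, replicate blocks, array weights, each array left out in turn, and an estimated correlation for the lists. With quantile normalization or an offset of 1 the brightest probe set of a gene was chosen anew and could be another one. The smallest p that 100000 permutations can give is 1e-05.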

Results

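Gene expression was measured in pancreatic islets isolated from young (5 weeks) and old (56 weeks) C57BL/6J mice, which the labels describe as male. Islets of each age were analysed fresh or after culture at 3, 5.5 or 11 mM glucose, and young islets also after culture at 16 mM. A time course took young islets from an overnight period at 3 mM glucose (time 0) to 1 h and 4 h at 11 mM. It had no group kept at 3 mM for the same hours, so its changes cannot separate glucose from hours of culture. Each of the 12 groups had 2 arrays, except young islets at 11 mM with 4, which gave 26 arrays and 12580 genes tested. The comparisons ask how islet gene expression follows the glucose concentration, how early that response begins, and how it and the culture itself depend on the age of the mice.

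The arrays fell into 2 sets that the labels do not name. The ratio of the 5' to the 3' signal of the Gapdh control was 1.03 to 1.48 on 12 arrays (set A) and 0.1 to 0.277 on 14 arrays (set B). All old islets and the fresh young islets lay in set A and the other young islets in set B, and young islets at 11 mM lay in both. Their replicates 1 and 2 correlated across genes at 0.983 and replicates 3 and 4 at 0.984, but the pairs correlated with each other at only 0.929 to 0.933, while other same-group pairs reached 0.975 to 0.989 (genes are not independent replicates). Between the pairs 4988 genes differed past the threshold. For each comparison that crosses the sets, the count from the fit with the array set as a block, chosen after the data were seen, is given too, with blocked values of genes and lists where stated.

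**Figure D1:**
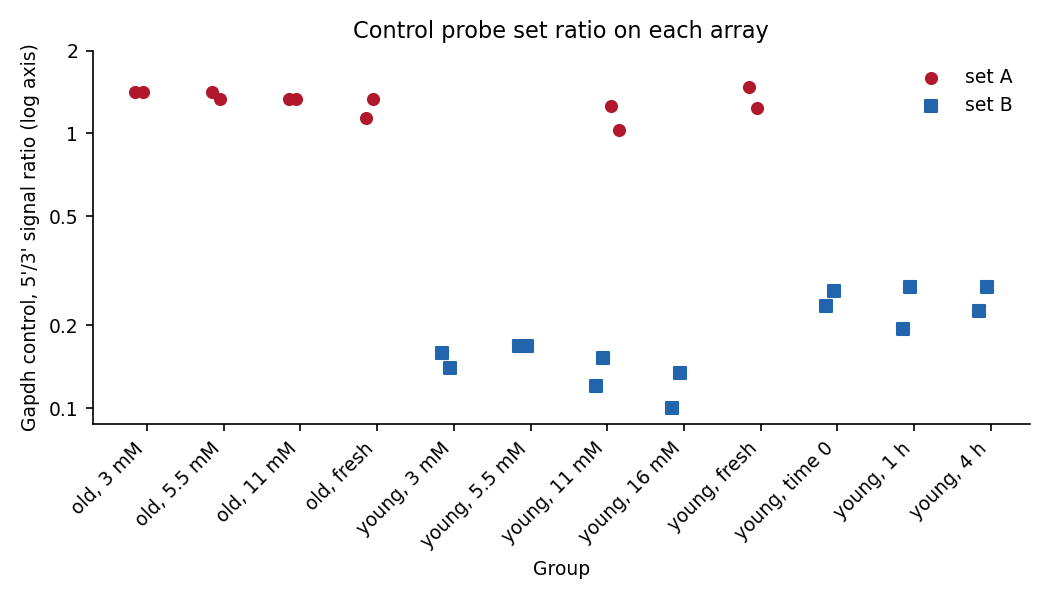
Ratio of the 5' to the 3' signal of the Gapdh control probe sets (log axis) on each of the 26 arrays, by group; circles are arrays of set A and squares arrays of set B. The 12 arrays of set A lie between 1.03 and 1.48, and young islets at 11 mM have 2 arrays in each set.

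Over the 26 arrays the signal of Gcg, which encodes glucagon, followed that of the cre-3 hybridization control, a spike added in the same amount to each array. Pearson's r was 0.976 and Spearman's rho 0.961 (permutation p = 1e-05 for both, the smallest that can be given, and 1.4e-05 after Benjamini-Hochberg adjustment over 10 genes). Its r was 0.967 without the 2 arrays farthest from the median, 0.991 within set A and 0.967 within set B. The r was 0.952 for Ttr, 0.94 for Sst, 0.93 for Ppy, 0.912 for Chga, 0.91 for Pyy, 0.89 for Iapp, 0.69 for Ins2, 0.65 for the glucose transporter gene Slc2a2 and 0.508 for the prohormone convertase gene Pcsk1. Changes of the hormone genes, Ttr and Chga are not given one by one, but they count as members of their lists. Calls of those lists may therefore share the variation of the control, which was not tested. Iapp is among the 9 beta cell genes that rose at 16 against 3 mM, and Chga among the 17 that rose at 11 against 3 mM over both ages.

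In young islets, 16 mM against 3 mM glucose raised genes of glucose sensing and hormone processing. Slc2a2 rose by 2.24 on the log2 scale (SE 0.37, n = 2 arrays per group), from a signal of 1166 ± 165 to 5549 ± 785. G6pc2, an islet glucose-6-phosphatase, rose by 2.44 (SE 0.27), Pcsk1 by 2.73 (SE 0.18), Sytl4, a granule protein, by 1.39 (SE 0.15) and the beta cell transcription factor Pdx1 by 1.59 (SE 0.34). Of the 22 measured genes of the beta cell function list, 9 rose and 13 did not pass, with 13 higher when adjusted over the list alone (camera adjusted p = 1.01e-07, adjusted p = 0.156 with an estimated correlation). Txnip, which encodes a thioredoxin-binding protein, rose by 2.25 (SE 0.21), the desaturase gene Scd2 by 1.89 (SE 0.26) and the ATP citrate lyase gene Acly by 1.06 (SE 0.21). These genes belong to the list of ChREBP targets and lipogenesis, ChREBP being a glucose-responsive transcription factor, in which 11 of 17 genes rose and 6 did not pass. In it 11 were higher and 1 lower when adjusted over the list alone (adjusted p = 1.89e-06, adjusted p = 0.0166 with an estimated correlation). With quantile normalization, which can change the probe set that stands for a gene, Acly was at 0.28 and did not pass (adjusted p = 0.0903, the highest over its alternatives). As the mean of probe sets Acly was at 0.69 and Scd2 at 1.13.

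The same comparison raised genes of cholesterol synthesis, protein folding and the cell cycle in young islets. Stard4 rose by 1.41 (SE 0.21) and Tm7sf2 by 1.24 (SE 0.25). In all 9 of 20 cholesterol genes rose while 11 did not pass (12 higher when adjusted over the list alone; camera adjusted p = 8.08e-07, adjusted p = 0.137 with an estimated correlation). Among endoplasmic reticulum (ER) chaperones and genes of the unfolded protein response, 8 of 24 rose, including Ero1b (1.22, SE 0.17), Sec24d (1.01, SE 0.15) and Pdia6 (0.70, SE 0.16). The other 16 did not pass (10 higher when adjusted over the list alone; adjusted p = 8.25e-05, adjusted p = 0.471 with an estimated correlation). The proliferation marker Mki67 rose by 1.77 (SE 0.33), from 47.5 ± 2.12 to 202.5 ± 40.3, Ccna2 by 1.29 (SE 0.24), Cdc20 by 1.25 (SE 0.25) and Ube2c by 1.16 (SE 0.23). Of 25 cell cycle genes 12 rose and 13 did not pass (14 higher when adjusted over the list alone; adjusted p = 8.25e-05, adjusted p = 0.397 with an estimated correlation). In the same arrays the median change of acinar cell markers was 0.20 and that of endothelial cell markers -0.07, and neither list passed. Pdia6 and Cdc20 did not pass without replicate 2 at 16 mM (adjusted p = 0.091 and 0.0523). Stard4 was at 0.80 and Ero1b at 2.17 as the mean of probe sets, and Ube2c at 1.83 with an offset of 1.

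Ddit3, which encodes the stress factor CHOP, was lower at 16 than at 3 mM in young islets. It fell by 3.93 (SE 0.27) from 3904 ± 4.95 to 242 ± 22.6. Fresh young islets, on arrays of set A, read 280 and 247 for Ddit3, nearer to 16 than to 3 mM. The difference may therefore lie in a higher level at 3 mM rather than a lower one at 16 mM. Nupr1 (-3.15, SE 0.22), Trib3 (-3.31, SE 0.35) and Ppp1r15a (-2.13, SE 0.24) were lower at 16 than at 3 mM as well. The ATF4 amino acid response list, which holds these 4 genes, did not pass as a whole: 6 of 26 members rose, 5 fell and 15 did not pass (7 higher and 8 lower when adjusted over the list alone; adjusted p = 0.756). The largest falls were those of Stbd1, a glycogen-binding protein (-4.58, SE 0.28), Ddit3, the ectonucleotidase gene Entpd2 (-3.80, SE 0.25), Steap1 (-3.41, SE 0.21) and the metallothionein gene Mt2 (-3.36, SE 0.25). The largest rises were those of Dapl1 (4.17, SE 0.38), Fer1l6 (3.32, SE 0.32) and Pdyn, the prodynorphin gene (3.12, SE 0.42). In all, 2272 genes changed at 16 against 3 mM, 1169 higher and 1103 lower, 698 of them at least 2-fold. Both groups lie in set B, where the numbers were taken to pair the arrays. The correlation of deviations between these 2 groups, 0.19, was within the 0.051 to 0.22 found between cultured young and old groups. The count was 3613 with the array set block and 4636 with a replicate block as well. It was 1092 or 1327 without replicate 1 or 2 at 3 mM and 1101 without replicate 2 at 16 mM.

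At 5.5 mM, the step above 3 mM, part of these genes had already moved at both ages. In young islets Slc2a2 rose by 1.72 (SE 0.37) and G6pc2 by 1.61 (SE 0.27), and in old islets by 1.70 (SE 0.37) and 1.79 (SE 0.27), with n = 2 arrays per group. Olfm4 rose at both ages, by 1.88 (SE 0.29) in old islets, and the phosphatase gene Dusp4 fell by 2.73 (SE 0.44) in young islets and fell by 2.04 (SE 0.44) in old islets. In young islets Ppp1r15a (-1.77, SE 0.24), Ddit3 (-1.37, SE 0.27), Nupr1 (-1.17, SE 0.22) and the glucose transporter gene Slc2a1 (-1.37, SE 0.31) fell. In old islets the small RNA host genes Zfas1 (-1.50, SE 0.17) and Snhg16 (-1.43, SE 0.22) fell. Whichever 1 of the 4 arrays was left out, Slc2a2 at either age (adjusted p = 0.0837 to 0.312), Nupr1 and Slc2a1 in young islets (0.0586 to 0.264) and Olfm4 and Dusp4 in old islets (0.0505 to 0.411) did not pass. In young islets G6pc2, Dusp4 and Ddit3 did not pass without either array at 3 mM or without replicate 2 at 5.5 mM (0.0535 to 0.301), nor did Olfm4 and Ppp1r15a without replicate 2 of either group (0.0535 to 0.137). In old islets G6pc2 and Snhg16 did not pass without replicate 1 at 3 mM (0.113 and 0.139) or replicate 2 at 5.5 mM (0.0873 and 0.147). As the mean of probe sets Snhg16 in old islets (-0.51, adjusted p = 0.14) and Ddit3 (-0.92, 0.12) and Slc2a1 (-1.15, 0.0914) in young islets did not pass. With only the arrays of the same experiment Nupr1, Ddit3 and Dusp4 did not pass in young islets (0.0696 to 0.122). Slc2a2 in old islets did not pass without a filter (0.0543) or a trend (0.0548).

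Of the 22 beta cell genes 3 rose at 5.5 mM in young and 2 in old islets, and when adjusted over the list alone 8 were higher and 1 lower in young and 8 higher in old islets. The list rose as a whole in both (camera adjusted p = 4.38e-05 and 4.97e-07, adjusted p = 0.612 and 0.594 with an estimated correlation). In young islets the ChREBP list was higher with 0 of 17 genes past limma's threshold over all genes and 3 when adjusted over the list alone (adjusted p = 0.00578, adjusted p = 0.268 with an estimated correlation). The ATF4 list was lower with 3 of 26 genes that fell, 4 when adjusted over the list alone (adjusted p = 0.00977, adjusted p = 0.693 with an estimated correlation). In total 149 genes changed in young islets (67 higher, 82 lower; 762 with the array set block and 1610 with a replicate block as well) and 83 in old islets (46 higher, 37 lower; 590 with the array set block). The young count was 16 or 2 without replicate 1 or 2 at 3 mM and 97 or 0 (limma) without replicate 1 or 2 at 5.5 mM, and the old count 1 or 30 and 11 or 1 in the same order.

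In old islets, 11 against 3 mM glucose raised genes of the beta cell, ChREBP and cholesterol lists. Slc2a2 rose by 2.90 (SE 0.37, n = 2 arrays per group) from 756 ± 86.3 to 5824 ± 1498, G6pc2 by 2.44 (SE 0.27), Pcsk1 by 1.77 (SE 0.18) and Sytl4 by 1.50 (SE 0.15). Txnip rose by 1.73 (SE 0.21), Scd2 by 1.46 (SE 0.26), the fatty acid synthase gene Fasn by 0.94 (SE 0.24) and Idi1 by 1.37 (SE 0.32). Fer1l6 (3.12, SE 0.32) and Prss53 (2.75, SE 0.28) were among the largest rises. Stbd1 (-3.16, SE 0.28), the angiopoietin-like gene Angptl6 (-2.76, SE 0.22), Ddit3 (-2.66, SE 0.27), Zfas1 (-2.55, SE 0.17), Nupr1 (-1.69, SE 0.22) and Trib3 (-1.54, SE 0.35) fell. Fasn did not pass without either array at 3 mM or replicate 2 at 11 mM (adjusted p = 0.054 to 0.124). Without replicate 1 of either group Idi1 (0.0925 and 0.0621) and Trib3 (0.0572 and 0.0566) did not pass. Scd2 was at 0.71 as the mean of its probe sets.

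Among the lists in old islets, 12 of 22 beta cell genes rose (14 when adjusted over the list alone; camera adjusted p = 6.48e-10, adjusted p = 0.116 with an estimated correlation). The ChREBP list had 9 of 17 genes that rose (10 when adjusted over the list alone; adjusted p = 0.000727, adjusted p = 0.112 with an estimated correlation). In the cholesterol list 5 of 20 rose by either adjustment, that over the list alone included (adjusted p = 0.00872, adjusted p = 0.615 with an estimated correlation). Of 24 ER chaperone genes 2 rose and 1 fell, and the list did not pass (1 higher when adjusted over the list alone; adjusted p = 0.752). No member of the cell cycle list passed, nor did the list (adjusted p = 0.811). Mki67 lay at 16.5 ± 2.12 and 5.5 ± 2.12, under the median signal of these arrays, and with an offset of 1 it passed as lower (-1.46, adjusted p = 0.0258). The comparison called 1734 genes, 976 higher and 758 lower (457 at least 2-fold), and 3090 with the array set block, which changes only the estimated spread here. Without replicate 1 or 2 at 3 mM the count was 540 or 948, and without replicate 1 or 2 at 11 mM 929 or 842.

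**Figure D2:**
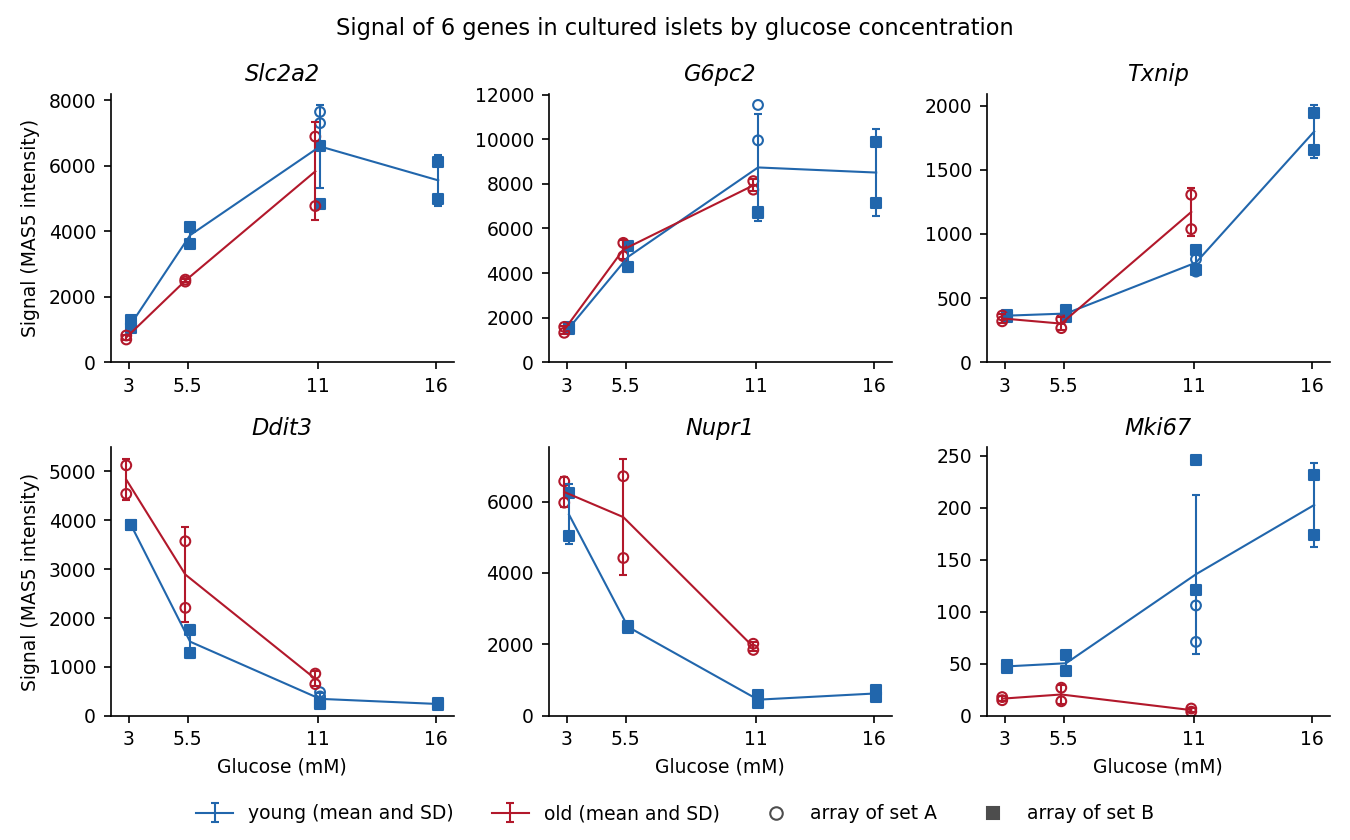
Signal (deposited MAS5 intensity) of 6 genes against the glucose concentration of the culture (mM); symbols are single arrays, open circles of set A and filled squares of set B, and lines with bars give the mean and SD of young (blue) and old (red) islets. Slc2a2 went from 1166 at 3 mM to 5549 at 16 mM in young islets, and Nupr1 from 6268 to 1932 between 3 and 11 mM in old islets.

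Young islets at 11 against 3 mM gave 3810 genes, 1781 higher and 2029 lower (877 at least 2-fold; n = 4 and 2 arrays). With the array set block, which amounts to comparing replicates 1 and 2 with 3 mM within set B, 3320 genes passed (1672 higher, 1648 lower), and 2488 passed with the same direction in both fits. Fer1l6 rose by 3.31 (SE 0.28; 3.29 with the array set block), Fmo1 by 3.03 (SE 0.29; 3.02) and Slc2a2 by 2.47 (SE 0.32; 2.27). Stbd1 (-4.49, SE 0.24; -4.43 with the block), Entpd2 (-3.91, SE 0.21; -3.64), Nupr1 (-3.62, SE 0.19; -3.58) and Ddit3 (-3.48, SE 0.23; -3.86) fell. The beta cell list had 14 genes that rose and Kcnj11, a potassium channel subunit gene, that fell (adjusted over the list alone 16 and 1; camera adjusted p = 4.88e-07, adjusted p = 0.241 with an estimated correlation). With the array set block 13 of the 22 rose and none of the 22 fell, and Kcnj11 did not pass (-0.15, adjusted p = 0.491). Kcnj11 also did not pass without either array at 3 mM or without replicate 3 or 4 at 11 mM (0.0698 to 0.358), nor as the mean of its probe sets (-0.16, 0.507). Of 17 ChREBP genes 9 rose and 1 fell (adjusted over the list alone 10 and 1; adjusted p = 0.000296, adjusted p = 0.0927 with an estimated correlation). Of 20 cholesterol genes 9 rose by either adjustment, that over the list alone included (adjusted p = 8.72e-05, adjusted p = 0.241 with an estimated correlation). Of 25 cell cycle genes 12 rose and 2 fell (adjusted over the list alone 13 and 2; adjusted p = 0.00361, adjusted p = 0.739 with an estimated correlation). With the array set block 11 rose and none of the 25 fell, with Ccna2 at 1.55 (SE 0.20; 1.45 with the block) and Top2a at 1.32 (SE 0.25; 1.51). Top2a was at 0.73 as the mean of its probe sets. The ATF4 list was lower (7 genes fell and 3 rose, adjusted over the list alone 8 and 3; adjusted p = 0.0245, adjusted p = 0.739 with an estimated correlation), a call that was lost with the array set block (adjusted p = 0.297). The count was 1769 or 1942 without replicate 1 or 2 at 3 mM.

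Averaged over both ages, 11 against 3 mM changed 4187 genes, 2173 higher and 2014 lower, and 4919 with the array set block. The water channel gene Aqp4 rose by 2.26 (SE 0.14), Plut, a long noncoding RNA next to Pdx1, by 2.33 (SE 0.20) and Olfm4 by 2.77 (SE 0.19). Cyb5r1 (-2.70, SE 0.12), Angptl6 (-3.08, SE 0.15), Dusp4 (-2.62, SE 0.29) and Depp1 (-2.44, SE 0.34) fell. Aqp4 was at 2.24 with the array set block, Plut at 2.45, Olfm4 at 2.63, Cyb5r1 at -2.61, Angptl6 at -2.96, Dusp4 at -2.44 and Depp1 at -2.11, and all 7 passed. Aqp4 was at 1.30 as the mean of its probe sets. Of the beta cell genes 17 of 22 rose and none of the 22 fell (18 higher when adjusted over the list alone; camera adjusted p = 8.65e-09, adjusted p = 0.164 with an estimated correlation). The ChREBP list had 11 of 17 genes that rose by either adjustment, that over the list alone included (adjusted p = 0.000127, adjusted p = 0.0633 with an estimated correlation). Of the cholesterol genes 13 of 20 rose (14 when adjusted over the list alone; adjusted p = 0.000127, adjusted p = 0.287 with an estimated correlation). In these lists 17, 11 and 14 genes rose with the array set block.

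The responses of young and old islets overlapped. Of the 3810 and 1734 genes, 628 rose and 566 fell at both ages, against 138 and 122 for independent lists of those lengths, and 4 went in opposite directions. Over the genes called in young islets the slope of the old on the young change was 0.57, and 0.73 with the array set block, which shared 1050 rises and 885 falls. The shared count of 1194 was 461 or 705 without replicate 1 or 2 of old islets at 3 mM, 670 or 673 without those at 11 mM, and 760 without replicate 1 of young islets at 3 mM. The difference between the ages was tested as an interaction, and Nupr1 alone passed: its fall was smaller in old islets by 1.93 (SE 0.29, adjusted p = 0.0264; 1.89 with the array set block). Its signal at 11 mM was 452.5 ± 113 in young (n = 4) and 1932 ± 122 in old islets (n = 2). At an unadjusted p under 0.05 the interaction gave 1635 genes in limma, and with the array set block 18 passed. As a list, cell cycle genes responded less in old than in young islets (median difference -0.63; 0 genes over all genes tested and 7 lower when adjusted over the list alone; camera adjusted p = 3.73e-06, adjusted p = 0.579 with an estimated correlation). Mki67 differed by -1.74 (SE 0.43, adjusted p = 0.183), and by -2.18 with the array set block, where it passed (adjusted p = 0.0218). The interaction count was 0 (limma) without either array of old islets at 3 or 11 mM, without replicate 2 of young islets at 3 mM or without replicate 3 at 11 mM. It was 2 without replicate 1 of young islets at 3 mM, and 118 or 7 without replicate 1 or 2 of young islets at 11 mM.

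Between 16 and 11 mM in young islets 2 genes passed: Txnip was higher at 16 mM by 1.20 (SE 0.18; n = 2 and 4 arrays) and Ampd3, an AMP deaminase gene, lower (-1.28, SE 0.20). The ER chaperone list was higher at 16 mM (median 0.41; 0 of 24 genes over all genes tested and 11 when adjusted over the list alone; camera adjusted p = 1.21e-05, adjusted p = 0.673 with an estimated correlation). Its members Pdia6 (0.76, SE 0.14, adjusted p = 0.0561) and Creld2 (0.99, SE 0.20, adjusted p = 0.059) did not pass alone, but did with an offset of 1 (0.0426 and 0.0484), the 75th percentile filter (0.0421 for both) or the array set and replicate blocks (0.0237 for both). The ATF4 list (median 0.44, adjusted p = 0.00403) and the oxidative phosphorylation list (0.19, 0.0108) were higher too (adjusted p = 0.673 with an estimated correlation for both). Markers of macrophages (median -0.41, adjusted p = 0.0108), of stellate cells and fibroblasts (-0.36, 0.00403) and of endothelial cells (-0.28, 0.0108) were lower in the same arrays (adjusted p = 0.761 with an estimated correlation for each). Adjusted over the list alone 9 ATF4 and 3 oxidative phosphorylation genes were higher and 2 endothelial genes lower. With the array set block the medians were 0.42 for the ER list, 0.12 for ATF4, 0.15 for oxidative phosphorylation and -0.23 for stellate cells, while macrophages (-0.06, adjusted p = 0.965) and endothelial cells (-0.10, 0.623) lost their calls. At an unadjusted p under 0.05 limma gave 2804 genes. Neither Txnip (1.16, adjusted p = 0.058) nor Ampd3 (-1.21, 0.166) passed with the array set block, with quantile normalization (0.0633 for both) or with only the arrays of the same experiment (0.122 and 0.405). As the mean of its probe sets Txnip was at 0.24 (adjusted p = 0.617), and with an offset of 1 Ampd3 was at -2.85. The 1 gene that passed with the array set block was Tle3 (-0.77, adjusted p = 0.0492), named here after its values were seen. With a replicate block as well 115 passed, Txnip and Ampd3 among them, but Ampd3 did not pass with the planned replicate block over all arrays (-1.21, adjusted p = 0.107). Neither of them passed without replicate 3 or 4 at 11 mM or replicate 2 at 16 mM (0.0554 to 0.168). The count rests on young islets at 11 mM from both sets: it was 2033 or 1952 without replicate 1 or 2, 0 without replicate 3, 4 or replicate 2 at 16 mM, and 62 without replicate 1 at 16 mM.

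Fresh islets of old and young mice lay in the same array set. Mki67 fell by 3.30 on the log2 scale from young to old islets (SE 0.33, n = 2 arrays per group), from 251 ± 38.2 to 11 ± 1.41, which is under the array median. Pbk (-3.30, SE 0.34), Top2a (-2.64, SE 0.29) and Cdc20 (-2.60, SE 0.25) fell, and so did Col3a1, a fibrillar collagen gene (-2.71, SE 0.28), Col1a2 (-1.95, SE 0.35) and Sparc (-1.71, SE 0.35). Higher in old islets were Bmpr1b, a receptor for bone morphogenetic proteins (2.84, SE 0.33), Nupr1 (2.47, SE 0.22), the immediate early gene Fosb (2.20, SE 0.30), Dusp1 (1.41, SE 0.25) and Chac1 (1.29, SE 0.25). Without replicate 1 of old islets Dusp1, Col1a2 and Sparc did not pass (adjusted p = 0.0795 to 0.111), nor Chac1 and Sparc without replicate 2 (0.138 and 0.111). Without replicate 1 of young islets Chac1, Col1a2 and Sparc did not pass (0.0587 to 0.134), nor Chac1 and Dusp1 without replicate 2 (0.0954 and 0.0793). With an offset of 1 Fosb did not pass (0.0885), and as the mean of probe sets Top2a was at -1.73. Of 25 cell cycle genes 12 fell and 13 did not pass (16 lower when adjusted over the list alone; camera adjusted p = 5.58e-21, adjusted p = 0.0107 with an estimated correlation). Of 22 markers of stellate cells and fibroblasts 6 fell (15 lower when adjusted over the list alone; adjusted p = 1.15e-16, adjusted p = 0.0663 with an estimated correlation).

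The ATF4 list was higher in fresh old islets with 3 of 26 genes that rose (7 when adjusted over the list alone; adjusted p = 3.02e-06, adjusted p = 0.132 with an estimated correlation). The immediate early list was higher too, with 5 of 24 that rose (9 when adjusted over the list alone; adjusted p = 5.07e-05, adjusted p = 0.148 with an estimated correlation). In the same arrays markers of acinar cells were higher in old islets by a median of 1.26, with 0 of 19 past limma's threshold by either adjustment, that over the list alone included (adjusted p = 0.000115, adjusted p = 0.406 with an estimated correlation). The change of the trypsin gene Prss3 depended on single arrays. It was 4.13 without replicate 1 and 0.59 without replicate 2 of old islets, and 1.30 without replicate 2 of young islets. Lower were markers of alpha cells (median -0.445, adjusted p = 0.00791, adjusted p = 0.277 with an estimated correlation), of delta and PP cells (-0.385, 0.0173, adjusted p = 0.277 with an estimated correlation) and of Schwann cells (-0.476, 0.0351, adjusted p = 0.29 with an estimated correlation). None of their members passed over all genes in limma, and 4 delta and PP markers were lower when adjusted over the list alone. The cre-3 control, which the hormone genes followed, read 13251 and 8519 in fresh old and 15072 and 15705 in fresh young islets. The calls of alpha and of delta and PP markers may share that difference, which was not tested. The Schwann cell call was lost with the array set block (adjusted p = 0.0517) and returned with a replicate block as well (adjusted p = 0.0343). In all, 266 genes differed, 125 higher and 141 lower in old islets, and 1188 with the array set block. Without replicate 1 or 2 of old islets the count was 46 or 91, and without replicate 1 or 2 of young islets 85 or 76.

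Averaged over fresh islets and culture at 3, 5.5 and 11 mM, old and young islets differed in 4924 genes, 2119 higher and 2805 lower in old islets, but the array sets differ between the ages at 3 and 5.5 mM and, for 2 of the 4 young arrays, at 11 mM. With the array set block 2492 genes passed, 1484 higher and 1008 lower. Of the 4924 genes, 1118 passed with the same direction in both fits, and 1085 had the opposite sign with the block. Bmpr1b (2.33, SE 0.16; 2.13 with the array set block), Nmnat2, an NAD synthesis enzyme gene (1.92, SE 0.10; 1.78), Reln (1.90, SE 0.18; 1.59), Clip4 (1.93, SE 0.12; 2.01), Nupr1 (1.46, SE 0.11; 1.50) and the cell cycle inhibitor gene Cdkn1b (1.82, SE 0.17; 0.98) were higher in old islets in both fits. Pam, with the largest rise of 2.34 (SE 0.42), was at 0.07 with the block (adjusted p = 0.851). Lower in both fits were Mki67 (-1.96, SE 0.16; -1.41 with the block), Mcoln3 (-1.90, SE 0.14; -2.12), Trim59 (-1.66, SE 0.10; -1.68), Col3a1 (-1.50, SE 0.14; -1.84) and the growth factor receptor gene Pdgfrb (-1.03, SE 0.09; -0.87). Cdkn1b was at 0.74 and Pdgfrb at -0.68 as the mean of probe sets.

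Of 22 markers of stellate cells and fibroblasts 18 fell over the 4 conditions, and 18 with the array set block (20 and 18 when adjusted over the list alone; camera adjusted p = 2.4e-09 and 1.32e-15, adjusted p = 0.382 and 0.194 with an estimated correlation). Of 25 cell cycle genes 17 fell, and 8 with the block (18 without it when adjusted over the list alone; adjusted p = 3.92e-06 and 0.000466, adjusted p = 0.382 and 0.457 with an estimated correlation). Macrophage markers were higher in old islets with 14 of 22 genes that rose, among them C1qa (1.01, SE 0.13), 16 when adjusted over the list alone (adjusted p = 3.92e-06, adjusted p = 0.541 with an estimated correlation). With the block 2 of 22 passed and the call was lost (adjusted p = 0.238). The ATF4 list passed only with the block (13 of 26 genes higher by either adjustment, that over the list alone included; adjusted p = 2.3e-06, adjusted p = 0.14 with an estimated correlation), against adjusted p = 0.155 without it. Glycolysis genes (higher, camera adjusted p = 0.00373) and alpha cell markers (lower, 0.00891) also passed only with the block, against 0.355 and 0.535 without it.

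Culture at 11 mM glucose, compared with fresh islets and averaged over both ages, lowered markers of acinar and endothelial cells. The elastase gene Cela3b fell by 6.92 (SE 0.78), in young islets from 4575 ± 1640 (n = 2) to 54.2 ± 34.4 (n = 4) and in old islets from 6196 ± 892 to 20 ± 26.9 (n = 2 each). The carboxypeptidase gene Cpb1 (-6.40, SE 0.51) and Zg16 (-6.09, SE 0.31) fell as well. Of 19 acinar markers 18 fell, with a median of -5.10, by either adjustment, that over the list alone included (camera adjusted p = 1.19e-31, adjusted p = 0.0132 with an estimated correlation). The vascular receptor gene Kdr (-3.36, SE 0.18), Plvap (-3.32, SE 0.18) and Ptprb (-2.55, SE 0.14) fell. All 15 endothelial markers fell by either adjustment, that over the list alone included (median -2.02; adjusted p = 4.04e-30, adjusted p = 0.00544 with an estimated correlation). H2-Aa (-2.68, SE 0.30) and H2-Eb1 (-2.42, SE 0.21), which encode MHC class II chains, fell as well. Blocked by array set, 18 acinar (median -5.24) and 15 endothelial markers (-1.87) fell, with Cela3b at -7.23, Kdr at -3.37, H2-Aa at -2.40 and H2-Eb1 at -2.23. With an offset of 1 the brightest probe set was chosen anew, and Cela3b was at -4.39. A smaller offset cannot shrink the fall of the probe set given above, so this value is of another probe set.

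Immediate early genes were higher in fresh islets: in culture Fos (-6.13, SE 0.28), Egr1 (-5.01, SE 0.19), Fosb (-2.72, SE 0.20) and Dusp1 (-2.26, SE 0.17) fell. Of 24 genes of that list 12 fell and 12 did not pass (12 lower and 2 higher when adjusted over the list alone; camera adjusted p = 8.38e-11, adjusted p = 0.0132 with an estimated correlation). Culture raised 20 of 26 ATF4 genes (23 when adjusted over the list alone; adjusted p = 7.37e-20, adjusted p = 0.00435 with an estimated correlation), among them Chac1 (2.06, SE 0.17), the serine synthesis gene Psph (1.57, SE 0.12) and the asparagine synthetase gene Asns (1.13, SE 0.10). It raised 9 of 16 oxidative stress genes, including Hmox1, which encodes haem oxygenase (2.04, SE 0.30), Gpx2 (1.26, SE 0.14) and Txnrd1 (1.08, SE 0.11); adjusted over the list alone 10 were higher and 3 lower (adjusted p = 4e-05, adjusted p = 0.135 with an estimated correlation). In the fit with the array set block 11 immediate early genes fell, 20 ATF4 and 10 oxidative stress genes rose, and Fos was at -6.41.

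Markers of stellate cells and fibroblasts went the other way from those of endothelial and acinar cells in culture. Of 22 such genes 12 rose, including Col5a2 (2.41, SE 0.16), the fibronectin gene Fn1 (2.25, SE 0.18) and Mgp (1.25, SE 0.18), and 2 fell (14 and 4 when adjusted over the list alone; camera adjusted p = 2.51e-05, adjusted p = 0.234 with an estimated correlation). Of these 15 rose and 3 fell with the array set block. The largest rises also held Gsdma, a gasdermin gene (2.95, SE 0.29), the galectin gene Lgals3 (2.82, SE 0.32) and the transcriptional inhibitor genes Id2 (2.40, SE 0.15) and Id3 (2.34, SE 0.11). Txnip was lower in culture at 11 mM than in fresh islets (fell by 1.19, SE 0.14). The comparison called 1144 genes (531 higher, 613 lower), 1170 with the array set block and 2023 with a replicate block as well. It called 730 without replicate 2 of old islets at 11 mM, 687 without replicate 1 of fresh old islets, and 1789 or 1851 without replicate 3 or 4 of young islets at 11 mM. In no gene did the culture response differ between the ages (limma, 924 genes at an unadjusted p under 0.05, smallest adjusted p = 0.0562; 3 genes with the array set block and 60 with a replicate block as well). That count of 0 became 5 without replicate 1 of fresh old islets and 3 without replicate 1 of fresh young islets.

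In young islets Atf4 (-0.75, SE 0.14, n = 2 arrays per group) and Slc38a2, an amino acid transporter gene (-0.64, SE 0.11), fell 1 h after the move from 3 to 11 mM glucose. Neither passed whichever 1 of the 4 arrays was left out (adjusted p = 0.138 to 0.775), without a trend (0.0695 for both), with the 75th percentile filter (0.0827 and 0.055) or with only the arrays of the same experiment (0.26 and 0.315). Atf4 also did not pass with an offset of 1 (0.0599), without a filter (0.0784) or as the mean of its probe sets (-0.38, adjusted p = 1). The lowest adjusted p in limma over the alternatives was 0.000932 for Atf4 and 0.00319 for Slc38a2. Between time 0 and 1 h Atf4 went from 2882 to 1655 in replicate 1 and from 3028 to 1844 in replicate 2. At 4 h Ddit3 fell by 3.24 (SE 0.27), from 3539 ± 201 to 365.5 ± 81.3, and Trib3 (-3.10, SE 0.35), Chac1 (-2.26, SE 0.25) and Ppp1r15a (-1.56, SE 0.24) fell too. Txnip rose by 1.45 (SE 0.21), Scd2 by 1.47 (SE 0.26), Fasn by 1.11 (SE 0.24) and the nuclear receptor gene Nr4a2 by 1.53 (SE 0.31) at 4 h. Slc2a2 was at -0.68 (SE 0.37, adjusted p = 0.394) at 4 h, and it passed as lower with a replicate block (adjusted p = 0.00146). Fasn and Nr4a2 did not pass without either array of time 0 or replicate 1 at 4 h (0.0572 to 0.14), and as the mean of probe sets Nr4a2 was at 0.78.

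**Figure D3:**
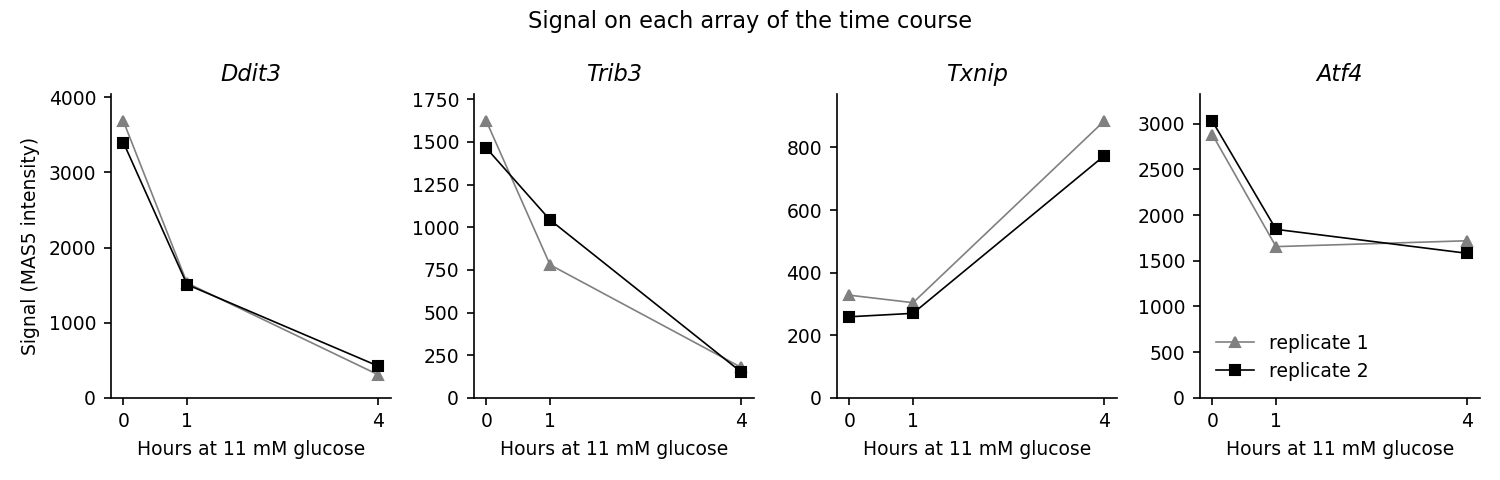
Signal (deposited MAS5 intensity) of 4 genes at time 0 and after 1 h and 4 h at 11 mM glucose in young islets; each line joins the arrays of 1 replicate number. Ddit3 went from a mean of 3539 at time 0 to 365.5 at 4 h, and Txnip from 293.5 to 828.5.

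The ATF4 list was lower at 1 h (1 of 26 genes fell, 3 when adjusted over the list alone; camera adjusted p = 5.49e-05, adjusted p = 0.287 with an estimated correlation). Its members Chac1 (-1.28, SE 0.25, adjusted p = 0.075) and Ddit3 (-1.21, SE 0.27, adjusted p = 0.124) did not pass at 1 h, but did with the array set block (0.00115 and 0.00688) and with a replicate block as well (0.000722 and 0.00411). It was lower again at 4 h (9 fell and 17 did not pass, 11 when adjusted over the list alone; adjusted p = 1.53e-11, adjusted p = 0.0391 with an estimated correlation). The ChREBP list was higher at 4 h, with 3 of 17 genes that rose by either adjustment, that over the list alone included (adjusted p = 0.0316, adjusted p = 0.242 with an estimated correlation, adjusted p = 0.0579 with the replicate block). At 1 h 8 genes changed (6 higher, led by Gm19325 at 2.16, SE 0.28, and Klhl30 at 1.96, SE 0.31), with 444 at an unadjusted p under 0.05. Gm19325 did not pass without replicate 2 of time 0 or replicate 1 at 1 h (adjusted p = 0.141 and 0.263), nor did Klhl30 whichever of the 4 arrays was left out (0.0884 to 0.626). With an offset of 1 (0.0599 and 0.304) or only the arrays of the same experiment (0.315 and 0.26) neither passed. At 4 h 621 changed, 311 higher and 310 lower, 155 of them at least 2-fold. The lncRNA Mir22hg (2.35, SE 0.23), Ager (2.33, SE 0.43), Nufip2 (1.64, SE 0.16) and Nme1 (1.63, SE 0.28) were among the largest rises. Klhl24 (-2.18, SE 0.25), Depp1 (-2.13, SE 0.52), N4bp2l1 (-2.07, SE 0.19) and Myc (-2.04, SE 0.31) were among the largest falls. Depp1 did not pass without either array of time 0 or replicate 1 at 4 h (0.0577 to 0.311), or with only the arrays of the same experiment (0.073). Ager did not pass without replicate 1 at 4 h (0.0731), nor Nme1 without replicate 2 of time 0 (0.0549). As the mean of probe sets Nufip2 was at 0.95, Nme1 at 0.94 and N4bp2l1 at -1.30, and with an offset of 1 Ager was at 3.52. With the replicate block, whose numbers pair these arrays, 76 genes passed at 1 h and 2242 at 4 h. Without replicate 1 or 2 the counts were 1 or 0 (limma) for time 0 and 0 or 2 for 1 h in the first comparison, and 202 or 179 for time 0 and 153 or 235 for 4 h in the second.

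The 4 h response overlapped with the response of young islets cultured for 2 days at 11 against 3 mM. Glucose and hours of culture change together in the former. Of 311 and 1781 genes that rose 155 were shared, against 44 for independent lists, and of 310 and 2029 that fell 189 were shared, against 50, while 12 went in opposite directions. Over the 621 genes of the 4 h response 88.2% had the same sign after 2 days and the changes correlated at 0.728 across genes. Ddit3, Trib3 and Depp1 fell and Txnip and Scd2 rose in both. The shared count of 344 was 692 with the array set block and 1161 with a replicate block as well. It was 207 or 215 without replicate 1 or 2 of young islets at 3 mM, 132 or 110 without those at time 0, and 97 or 156 without those at 4 h.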

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

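The test of a wrong label for replicates 3 and 4 of young islets at 11 mM, the separate tests of acinar and of ductal markers and the fits with the array set block were chosen only after the results were seen. Among 75 named genes whose 4 arrays of young islets at 11 mM were examined, 5 had 1 array far from the other 3 by Dixon's ratio, where chance gives about 1 in 20. The ratio was 0.838 for Aqp4, with a signal of 332 on replicate 4 against 279 to 287. It was 0.983 for Hsd17b7 (187 on replicate 2 against 111 to 112), 0.832 for Mcoln3 (71 on replicate 2 against 114 to 125) and 0.931 for Pdia6 (3320 on replicate 2 against 2766 to 2801). For Zg16 it was 1, with 7 on replicate 3 against 2, which lies far under the array median.

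The response to 11 against 3 mM glucose differed between old and young islets for Nupr1, by 1.93 (adjusted p = 0.0264 in limma). That call was lost without either array of old islets at 3 mM (adjusted p = 0.162 and 0.127) or at 11 mM (0.0834 and 0.367), without replicate 2 of young islets at 3 mM (0.252) and without replicate 3 at 11 mM (0.0522). It was also lost without an intensity trend (0.0683) and with only the arrays of the same experiment (0.119).

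In camera 3 lists differed in the same response. The median difference, old minus young, was 0.51 for the ATF4 list (adjusted p = 0.00216, adjusted p = 0.579 with an estimated correlation), and 0.11 with the array set block (adjusted p = 0.0163). It was -0.63 for the cell cycle list (adjusted p = 3.73e-06, adjusted p = 0.579 with an estimated correlation). It was -0.23 for endothelial markers (adjusted p = 0.0483, adjusted p = 0.762 with an estimated correlation), a call that was lost with the array set block (median -0.003, adjusted p = 0.473). The same block added calls in camera for cholesterol synthesis (lower, adjusted p = 0.0183) and oxidative phosphorylation (higher, adjusted p = 0.0316).

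The response to culture differed between the ages for 9 lists in camera, and with an estimated correlation none of the 9 passed (adjusted p = 0.216 to 0.578). The median difference, old minus young, was 0.29 for beta cell genes (adjusted p = 0.0245), -0.285 for the ATF4 list (0.0498) and 0.22 for ER chaperones (0.00128). It was 0.55 for the cell cycle list (7.23e-05), -0.33 for immediate early genes (0.000143) and 0.17 for oxidative phosphorylation (0.000143). In fresh old islets Mki67 read 10 and 12, under the array medians of 38 and 37, so it had little room to fall in culture. Delta and PP cell markers were at 0.36 (0.0245), acinar markers at -1.73 (6.9e-07) and macrophage markers at 0.47 (0.00221). Hormone genes followed the cre-3 control, so the call of delta and PP markers may share its variation, which was not tested. With the array set block the beta cell, ATF4, delta and PP cell and macrophage calls were lost (adjusted p = 0.411, 0.741, 0.309 and 0.518). It added camera calls for glycolysis (higher, adjusted p = 0.00645), cholesterol synthesis (lower, 0.0144) and endothelial markers (lower, 0.0389).

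Replicates 1 and 2 of young islets at 11 mM differed from replicates 3 and 4 in 4988 genes, 3037 of them higher in replicates 1 and 2. The authors' scaling is argued against, since 5164 genes differed after quantile normalization. A wrong label, with replicates 3 and 4 being fresh islets, is argued against by markers of acinar cells at a median of -4.57 (quartiles -5.25 to -2.87, 19 genes) and of endothelial cells at -1.745 (quartiles -2.09 to -0.91, 15 genes) against fresh young islets. This test was first set on immediate early genes alone, whose median of -0.45 is what a wrong label would give, and the marker lists and their bounds were chosen after values had been seen. A difference in RNA quality or labelling stays open as a candidate explanation: over 5989 genes the changes of 2 probe sets of a gene correlated at 0.291 for the set difference and 0.574 for 16 against 3 mM glucose (a difference of -0.284), and separate islet preparations were not tested.

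Cell cycle genes rose from 3 to 16 mM in young islets by a median of 0.70 (quartiles 0.02 to 1.19). Markers of endothelial, stellate, macrophage and ductal cells did not rise alongside. Endothelial markers lay at -0.065 (quartiles -0.36 to 0.04), stellate markers at -0.12 (-0.21 to 0.15) and macrophage markers at -0.15 (-0.32 to 0.03). All were below the bound of 0.35, and ductal markers lay at -0.15 (quartiles -0.33 to -0.01). This argues against a larger share of these cells at 16 mM. Marker levels do not measure division, so division within these cell types is not excluded. Acinar cells cannot be told apart from islet cells here, because their markers lay at 0.20 with quartiles of 0.09 to 0.63 on both sides of that bound. Division of endocrine cells may contribute and was not tested.

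The arrays were also split in other ways within age or condition, and the median of those splits was 0 genes. These splits treat all arrays as exchangeable although the 2 array sets differ, so a small share of splits cannot exclude chance. For 11 against 3 mM over both ages 2 of 90 splits, the real one included, gave at least the real 4187 genes. The highest other split, with 4788, set replicates 3 and 4 of young islets at 11 mM against replicates 1 and 2 and the 3 mM arrays, which follows the array sets. It also exchanged all old islets at 3 and 11 mM, so that their contrast stays in it with the sign turned and its count is not from the sets alone. The value with the array set block was 4919. For age over 4 conditions 3 of 100 splits drawn from 3240, the real one included, gave at least 4924. At 3 and 5.5 mM the ages lie in different array sets, so this count cannot tell age from set. The highest other, with 6367, exchanged old islets at 3, 5.5 and 11 mM with young ones but left replicates 3 and 4 at 11 mM with the old islets. This also follows the sets but keeps the contrast of age at 3 and 5.5 mM with its sign turned, and the blocked value was 2492. For culture 7 of 90 splits gave at least 1144, so chance is not excluded by this count. The highest other, with 4616, set fresh young islets together with replicates 3 and 4 against replicates 1 and 2 at 11 mM, which follows the sets and points to that structure of the arrays. It also exchanged all old islets at 11 mM with fresh old islets, so that their contrast stays in it with the sign turned and the count is not from the sets alone. The blocked value was 1170.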

How the results depend on the processing

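The array set blocks were chosen only after the data were seen. Counts are genes past the threshold, and the cause of a move was not tested unless stated. Listed in order are 5.5 mM young, 16 mM young, 5.5 mM old, 11 mM old, fresh age, 1 h and 4 h, with 149, 2272, 83, 1734, 266, 8 and 621 genes. The array set block, which lowers the estimated spread within a set, gave 762, 3613, 590, 3090, 1188, 33 and 1428. With a replicate block within each set as well they were 1610, 4636, 1447, 4161, 2289, 76 and 2242, and with a replicate block over all arrays 896, 3829, 724, 3327, 1380, 38 and 1563. The latter block joins fresh young islets to arrays of the other set by number, and gave 5025 for culture and 3012 for its difference between ages. The replicate block within each age and experiment gave 1421, 4432, 1268 and 3929 for the first 4, then 63 at 1 h and 2073 at 4 h. Array weights gave 772 (5.5 mM young), 1280 (5.5 mM old), 2886 (11 mM old), 1185 (fresh age), 31 (1 h) and 1483 (4 h). Using only the arrays of the same experiment, and so fewer samples, gave 13, 1182, 807, 3385, 172 and, in limma at 1 h, 0, and 2210 against 3810 for 11 mM young.

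For 16 against 11 mM (2 genes) the count was 1 with the array set block, 115 with the replicate block as well, 57 with the replicate block within age and experiment and 1473 with array weights. It was 32 with an offset of 1, 60 with the 75th percentile filter, 1 with mean probe sets, and 0 with quantile normalization or the same experiment. For the difference between ages in the glucose response (1 gene) it was 18 with the array set block, 149 with both blocks, 24 with the replicate block over all arrays and 976 with array weights. It was 2 with mean probe sets and 0 without trend or with the same experiment. Culture (1144) gave 2023 with both blocks and 689 with the 75th percentile filter. Its difference between ages (0) gave 3 with the array set block, 60 with both blocks, and 1 with quantile normalization, no filter or no trend. Age over 4 conditions (4924) gave 2492 with the array set block. The 75th percentile filter, which tests fewer genes, gave 147 (5.5 mM old), 175 (fresh age) and 0 (1 h), quantile normalization 129 (5.5 mM old) and an offset of 1 gave 4 (1 h).

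Shared genes of 4 h and 2 days (344) were 692 with the array set block, 1161 with both blocks, 774 and 1067 with the replicate blocks and 668 with array weights. Those of young and old (1194) were 1935, 2659, 2098 and 2506 in the first 4 of these. Of 76 list calls 8 held with an estimated correlation. The array set block ended 11 list calls and added 9 (74 in all), and the replicate block then ended 1 and added 9 (82). In comparisons within set B these were the ChREBP list at 4 h, lost, and delta and PP cell markers at 16 against 3 mM, gained (adjusted p = 0.0411). Among named genes and lists the array set block ended 9 calls and added 5, and both blocks ended 7 and added 12. Old islets do not meet the pairing rule (0.056 to 0.2).

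Leaving out 1 array assumes that the lone array left varies like the other groups. It gave 0 to 97 genes (5.5 mM young), 1769 to 4880 (11 mM young), 1092 to 1697 (16 mM), 0 to 2033 (16 against 11 mM), 1 to 30 (5.5 mM old) and 540 to 948 (11 mM old). It gave 3107 to 4804 over both ages, 0 to 118 for the difference, 46 to 91 (fresh age), 4233 to 5468 (age), 687 to 1851 (culture) and 0 to 5 for its difference. It gave 0 to 2 (1 h), 153 to 235 (4 h), and 97 to 441 and 461 to 1300 shared genes. Of 1490 such fits of 211 named results 145 lost and 11 gained a call, and 0 reversed in limma. Signals under the array median, such as those of Mki67 in old islets, limit what can be read of dim genes, whose log2 changes understate the change.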

Other observations

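The test of a shared pool in the time course, the choice of the Y-linked gene that tests female RNA and the fits with the array set block were chosen only after the results were seen, and the genes named here were picked after their values were seen. In young islets the metallothionein genes Mt1 (-3.31, SE 0.42) and Mt2 (-3.36, SE 0.25), which encode metal-binding proteins, fell at 16 against 3 mM (n = 2 arrays per group), Mt2 from 5446.5 ± 54.5 to 532 ± 178. In old islets Mt2 fell by 1.57 (SE 0.25) at 11 against 3 mM, to 2197 ± 437, while Mt1 (-0.91, SE 0.42) did not pass (adjusted p = 0.174) but did with the array set block (0.0429). The young changes above are for 16 mM and cannot be set against these, so the ages were compared at 11 against 3 mM. The difference between the ages in this response of Mt2 was 1.28 (SE 0.34) and did not pass in limma (adjusted p = 0.221, 0.00918 to 0.578 over its alternatives). It passed with array weights (adjusted p = 0.0184), with the array set and replicate blocks (1.33, adjusted p = 0.00918) and without replicate 1 of young islets at 11 mM (1.43, adjusted p = 0.0422).

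Genes of the circadian clock were lower 4 h after the move to 11 mM glucose. Of 18 measured genes 3 fell and 15 did not pass, with 5 lower when adjusted over the list alone (camera adjusted p = 0.000783, adjusted p = 0.0391 with an estimated correlation). Ciart (-1.39, SE 0.33), Rora (-0.98, SE 0.25) and Bhlhe40 (-0.97, SE 0.20) fell, and Bhlhe40 also fell by 0.85 (SE 0.20) at 11 against 3 mM in old islets, a call that was lost without replicate 2 at 3 mM (adjusted p = 0.0803). At 1 h the list was lower too, with 0 of 18 genes past limma's threshold and 1 when adjusted over the list alone (adjusted p = 0.00262, adjusted p = 0.132 with an estimated correlation). Hours of culture and glucose change together in these groups, and no group was kept at 3 mM for the same hours. Without any 1 of the 4 arrays Ciart (adjusted p = 0.084 to 0.136) and Rora (0.106 to 0.182) did not pass, and Bhlhe40 did not pass without replicate 2 at time 0 or at 4 h (0.0891 and 0.081). Ciart did not pass with an offset of 1 (0.0586), and as the mean of probe sets Rora was at -0.60.

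The immunoglobulin genes Igha (3.655, SE 0.65) and Igkv8-30 (3.08, SE 0.65) had the largest rises among the genes past the threshold from young to old in fresh islets. The signal of Igha was 971 ± 1174 on the 2 old arrays and 28.5 ± 19.1 on the young ones. Its change was 1.89 without replicate 2 of old islets, and it did not pass without replicate 1 of young islets (adjusted p = 0.0787). Igkv8-30 did not pass without either of these (adjusted p = 0.199 and 0.189) or with an offset of 1 (3.81, adjusted p = 0.148), and was at 4.77 without replicate 1 of old islets.

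Xist, the RNA of the inactive X chromosome, read 2245 to 2696 on the 3 arrays of replicate 1 of the time course, whose mice the labels call male. It read 4 to 12 on those of replicate 2 and 1 to 19 on the other 20 arrays. The Y-linked genes were lower in replicate 1 than in replicate 2, with Eif2s3y at 137 to 204 against 724 to 833, Kdm5d at 20 to 36 against 132 to 157 and Uty at 25 to 31 against 181 to 187.

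Whether replicate 1 held RNA of female mice alone cannot be decided from these genes. The ratio of replicate 1 to replicate 2 of Eif2s3y, 0.177 to 0.267, lay above the bound set in advance for female RNA alone, which was 0.1. That goes against female RNA alone, but it rests on 1 gene chosen after the results were seen, and signal of its X-linked homolog was not tested. Replicate 1 read Kdm5d and Uty at about the array medians of 29 to 34, a level that female RNA alone would also give. Their ratios decide nothing, since such signals lie above what that bound would need. That each number is 1 pool of islets split over the 3 times is a candidate explanation for the shared pattern, as the differences between the replicates correlated at 0.55 or more between times.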
